A study of Sus scrofa with 28 samples.

How the data were processed

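RNA from the left apical, median and caudal lung lobes of anesthetized swine was measured on the Affymetrix porcine array. The animals had inhaled air or sulfur mustard vapor for 10 min, and the lobes were taken 12 h later. The 28 arrays came from 10 animals, of which 3 breathed air, 3 received a low dose of 60 µg/kg and 4 received a medium dose of 100 µg/kg. Medium animal 39 had no caudal array and medium animal 41 no apical array. The labels gave no scan date, no batch and no sex.

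The deposited values were signal intensity per probe set on a linear scale, 1 column per array. The mean signal after leaving out the lowest and highest 2% of probe sets was 150 on every array, as after scaling each array by 1 factor, and whether other steps came before was not known. The summarization software and the scaling target chosen by the authors were not given in the sources used here. Median signal ranged from 55.4 to 64.2 between arrays and the highest signal from 3360 to 5495. Mean correlation of an array with the others ranged from 0.968 to 0.982.

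The table held 24123 probe sets. After 124 control probe sets were left out, 23999 were tested without a filter on brightness. The supplied annotation gave 1 gene symbol for 10069 of these and several for 198, and did not list 13732. The 10069 covered 6765 symbols, and 2261 symbols had more than 1 probe set. In gene lists and for named genes, a gene was represented by its probe set with the highest mean over the 28 arrays.

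Signals were used as log2(signal + 16). Lower quartiles differed by up to 0.317 between arrays on this scale, above the limit of 0.2 set for adding quantile normalization, so the arrays were quantile normalized. Tests used limma 3.58.1 in R 4.3.3, and tables and figures were prepared with Python 3.11.15. Differences are log2 differences with standard errors from limma.

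The animal was the replicate in the exposure comparisons. Each animal's value was its coefficient in a linear model of the 28 arrays on animal and lobe. The lobes of an animal had a consensus correlation of 0.335. The 3 groups were fitted together with limma's lmFit and eBayes, and low minus air, medium minus air and medium minus low were taken from this fit. Exposure was also tested in each lobe by a separate fit with 1 array per animal. Lobes were compared over the 28 arrays with the animal as a fixed block. The interaction of exposure and lobe used the moderated F test of 4 coefficients in the same blocked design. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum.

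Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 36 lists of pathway genes and cell type markers with at least 3 measured members. The test was repeated with the correlation estimated from the data, under which 0 of the 36 lists passed in any of the 6 contrasts. Counts of members are given over all probe sets and adjusted over the list alone. Lists share genes in places, such as DUSP1 and PLAU.

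Named genes followed a rule. In exposure contrasts it took the 10 genes with the largest rise and the 10 with the largest fall among those called, with 6 and 6 in lobe contrasts and in medium versus low. It added up to 4 called members of each list that passed and up to 2 of other lists. Where under 10 genes were called it added the 5 with the smallest p, and it took 6 genes for the interaction. CXCL8, IL6, IL1B, CDKN1A, HMOX1 and SFTPC were given in each exposure contrast whatever their p, while MDM2 and SCGB1A1 were not measured under a single symbol. The comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined. Alternatives chosen after seeing the data were the deposited scaling, an RNA integrity covariate, gene lists under other scalings, and the 8 animals with all 3 lobes for lobe, interaction and list tests.

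An index of RNA integrity, higher where RNA is less intact, was taken as the mean log2 ratio of 3' to 5' signal of the actin and GAPDH control probe sets. It was compared between groups by exact permutation, two-sided. Alternatives to the choices above were median-centred arrays, the brighter part of the probe sets, an offset of 1, trend and robust eBayes, other ways to model the animal, only the groups compared, only the air animals for lobes, and leaving out each animal in turn. The number of arrays limits the precision of every value.

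The steps were tested on simulated data, drawn with the spread of each probe set within and between animals and with known changes in 100 probe sets per size. A log2 change of 1 was called for 83 of 100 in medium versus air, for 76 in the median lobe and for 80 in the interaction, and a change of 0.5 for 88 in apical versus median. Other calls numbered 9 in medium versus air, 24 in the median lobe, 7 in the interaction and 15 in apical versus median, each of 23999. A list of 6 genes raised by 0.5 was called by camera with an adjusted p of 7.36e-10, and 0 of the other lists passed. Probe sets were drawn independently of each other, so these data could not show false calls that arise when genes vary together.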

Results

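Gene expression was measured in 28 lung samples from 10 swine 12 h after a 10 min inhalation of air or sulfur mustard vapor, an alkylating agent that injures the airways. The apical, median and caudal lobes of the left lung were sampled in 3 air animals, 3 low-dose animals (60 µg/kg) and 4 medium-dose animals (100 µg/kg), except that 2 medium animals each lacked 1 lobe. Values are log2 differences with the standard error, and the n of a comparison is the number of animals. Arrays had median signals from 55.4 to 64.2. The 3' to 5' index of RNA integrity, higher where RNA is less intact, was highest in medium animal 39. It was 2.22 there, against 0.62 to 1.35 in the other 9 animals. Its mean was 1.25 in medium and 1.12 in air animals, a difference of 0.12 (exact permutation p = 0.886, two-sided, 35 splits). Low animals had a mean of 0.76, a difference of -0.36 from air (exact permutation p = 0.3, two-sided, 20 splits). With 3 against 3 animals this test cannot reach a p under 0.05. Medium animals were 0.48 above low animals (exact permutation p = 0.343, two-sided, 35 splits). Whether the index bears on the gene lists in the comparisons with the low animals was not tested.

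The comparison of low dose with air asks how lung expression differed after the smaller dose. KRT19, a keratin of airway epithelium, had the smallest p among named genes, with a difference of 0.74 ± 0.11 (adjusted p = 0.308, 3 against 3 animals). IPO5, an importin of nuclear transport, differed by 0.59 ± 0.10 (adjusted p = 0.453), SPAG9 by 0.40 ± 0.08, CLDN14 by 0.38 ± 0.08 and TRPT1 by -0.89 ± 0.18 (adjusted p = 0.526 for each). CLDN14 (mean signal 12.0 in low, 5.45 in air animals) and TRPT1 (13.4 and 38.3) were dim. Over the other settings CLDN14 ranged from 0.31 to 1.14 and TRPT1 from -1.49 to -0.76. None of these passed, although with all arrays under a random animal effect KRT19 and TRPT1 did (adjusted p = 0.0122 for each). That fit draws in part on lobes of the same animal, which can lower its p, here and below. Among the genes given whatever their p, the neutrophil chemokine CXCL8 differed by -0.30 ± 0.20, IL6 by 0.21 ± 0.25 and IL1B by -0.14 ± 0.12. The cell cycle inhibitor CDKN1A differed by 0.21 ± 0.21 and the heme oxygenase HMOX1 by -0.14 ± 0.18. SFTPC, a surfactant protein of alveolar type 2 cells, differed by 0.01 ± 0.07, and by -0.10 with median-centred arrays or -0.07 with the deposited scaling. With limma, 0 of 23999 probe sets were called in low versus air, while 1780 had an unadjusted p under 0.05 and 28 were called under the random animal effect.

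Of the 36 gene lists, 5 passed camera in low versus air. The airway secretory markers rose as a list, with a median of 0.17 over 11 genes, 9 of them above 0 (adjusted p = 0.00326; adjusted p = 0.205 with an estimated correlation). KRT19 and the tight junction gene CLDN4 (0.52 ± 0.14) passed when adjusted over the list alone. The ciliated cell markers rose by a median of 0.22, with 7 of 7 genes above 0 (adjusted p = 0.00886; adjusted p = 0.892 with an estimated correlation). ROPN1L (0.49 ± 0.12) passed adjusted over the list alone. The smooth muscle list rose by a median of 0.15 with 10 of 11 genes above 0 (adjusted p = 0.00326; adjusted p = 0.892 with an estimated correlation). Its contractile genes ACTG2 (0.49 ± 0.14) and CNN1 (0.45 ± 0.19) did not pass, nor did any other member adjusted over the list alone. Immediate early genes, which are transcribed within minutes of a stimulus, rose by a median of 0.13 with 12 of 15 above 0 (adjusted p = 0.0253; adjusted p = 0.892 with an estimated correlation). FOS (0.95 ± 0.27) and the phosphatase gene DUSP1 (0.60 ± 0.17) passed adjusted over the list alone. B and plasma cell markers fell by a median of 0.38 on the log2 scale over 3 genes (adjusted p = 0.0125; adjusted p = 0.892 with an estimated correlation). The immunoglobulin joining chain JCHAIN (-0.23 ± 0.07) passed adjusted over the list alone. In each of the 5 lists 0 members were called over all probe sets. Without low animal 32, 4 of the 5 calls ended (adjusted p = 0.0612 for B and plasma cell and for airway secretory markers, 0.447 for immediate early genes, 0.29 for ciliated markers). The medians were then 0.07 for ciliated markers, 0.07 for immediate early genes, 0.12 for airway secretory and -0.41 for B and plasma cell markers. The smooth muscle call ended without air animal 28 (0.09, adjusted p = 0.0658), that of the ciliated markers without air animal 44 (0.15, adjusted p = 0.0887) and that of immediate early genes without air animal 29 (0.03, adjusted p = 0.602). Immediate early genes had 0.24 without air animal 44 and 0.31 without low animal 33. Without low animal 31 the ciliated markers had 0.40 and the airway secretory markers 0.28.

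The medium dose was compared with air as the test of the larger dose. F3, which encodes tissue factor, the starter of blood coagulation, rose by 1.26 ± 0.17, from a mean signal of 423 in 3 air animals to 1033 in 4 medium animals (adjusted p = 0.0328). FBXO32, a ubiquitin ligase known from muscle wasting, fell by 1.74 ± 0.19 on the log2 scale, from 269 to 69.2 (adjusted p = 0.0197). PMAIP1, a p53 target that promotes apoptosis, rose by 0.91 ± 0.14 (adjusted p = 0.0488), and RCAN1, an inhibitor of calcineurin, by 0.77 ± 0.09 (adjusted p = 0.0201). MUC1, a mucin of the epithelial surface, fell by 0.74 ± 0.08 on the log2 scale (adjusted p = 0.0197). Each of these had 4 of 4 medium animals on that side of the air mean. The low animals lay between the groups for F3, at 0.66 ± 0.18 over air, and for FBXO32, at -0.93 ± 0.20. Neither was called in low versus air (adjusted p = 0.655 for F3 and 0.528 for FBXO32), and these values were chosen after they were seen.

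Further named genes that rose with the medium dose were NUDT6 (1.06 ± 0.11, adjusted p = 0.0197), the proline synthesis gene PYCR1 (0.89 ± 0.13, adjusted p = 0.0488) and TSKU (0.84 ± 0.11, adjusted p = 0.0328). Smaller rises were those of the nucleoside diphosphate kinase NME1 (0.62 ± 0.09, adjusted p = 0.0395), the mitochondrial ribonuclease PNPT1 (0.53 ± 0.07, adjusted p = 0.0289) and the collagen COL8A1 (0.50 ± 0.07, adjusted p = 0.0418). A second probe set for NUDT6, one for MUC1 and 2 of 3 further probe sets for COL8A1 pointed the other way. A further 7 symbols were called only through a probe set other than the gene's brightest, and these were chosen after their values were seen. Among them, TNFRSF12A, the receptor of the cytokine TWEAK, had 1.60 ± 0.18 (adjusted p = 0.0201) against 0.88 at its brightest probe set (adjusted p = 0.0683). CKAP4 had 0.89 ± 0.12 (adjusted p = 0.0328) against 0.64 (adjusted p = 0.0633). TNS3 had -0.75 ± 0.08 (adjusted p = 0.0197) against -0.34 (adjusted p = 0.156). PPID had -0.58 ± 0.08 (adjusted p = 0.0375) against 0.28 in the other direction, and NSL1 -0.63 ± 0.07 (adjusted p = 0.0197) against -0.01. RIPOR1 (-0.66 against -0.20) and BZW2 (0.52 against 0.19) were the other 2.

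**Figure D1:**
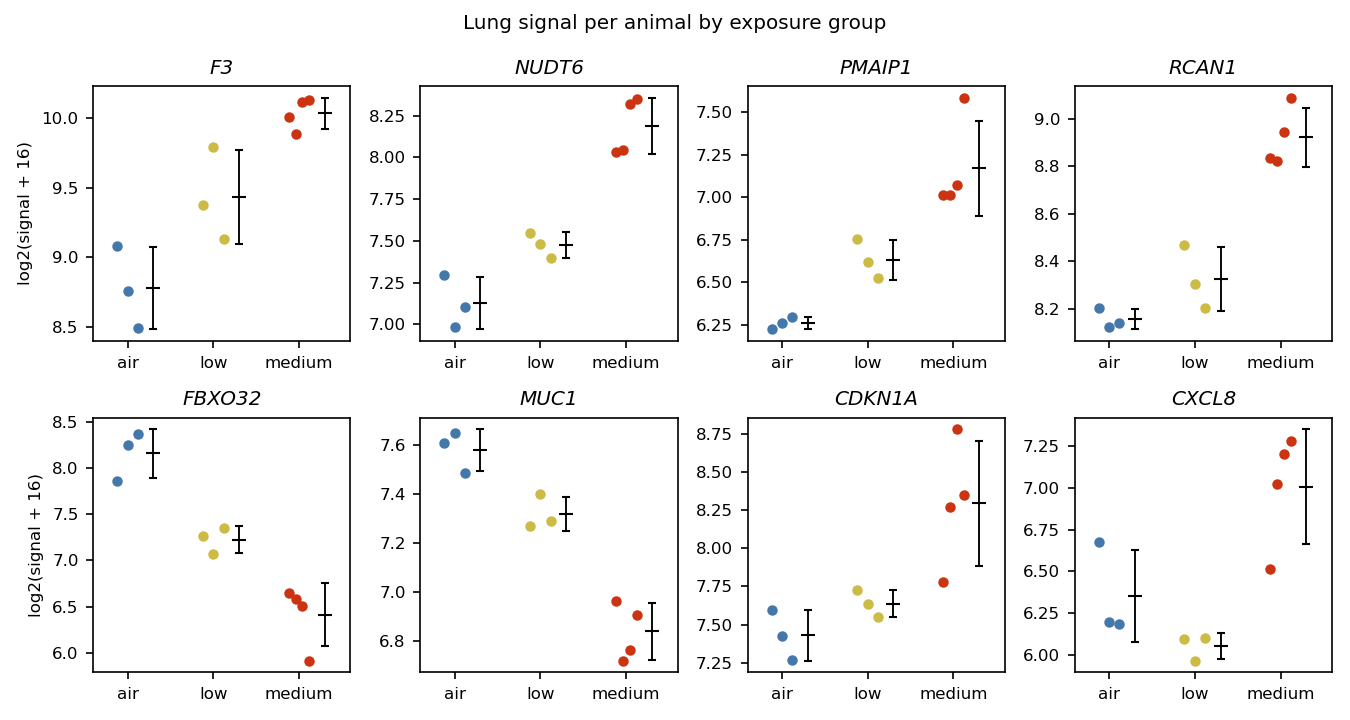
Signal of 8 genes per animal, as log2(signal + 16) on the vertical axis at the mean of the lobes, in 3 air, 3 low and 4 medium animals, with points for animals and a bar for the group mean and SD. Means of F3 were 8.78 in air and 10.04 in medium animals and those of FBXO32 8.16 and 6.41, while CDKN1A and CXCL8 were not called.

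The genes given whatever their p did not pass in medium versus air. CDKN1A differed by 0.86 ± 0.19 (adjusted p = 0.0951), CXCL8 by 0.65 ± 0.18 (adjusted p = 0.137) and IL6 by 0.46 ± 0.24 (adjusted p = 0.359), each with 4 of 4 medium animals above the air mean. Without medium animal 34, CDKN1A (1.04, adjusted p = 0.0276) and CXCL8 (0.82, adjusted p = 0.0377) passed, and CDKN1A also did under the random animal effect (0.84, adjusted p = 0.00377). IL1B differed by -0.11 ± 0.11 (adjusted p = 0.677), HMOX1 by 0.04 ± 0.17 (adjusted p = 0.938) and SFTPC by 0.06 ± 0.06 (adjusted p = 0.686). Without air animal 29 the HMOX1 difference was -0.13 and without medium animal 34 it was -0.05.

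With limma, 31 probe sets were called in medium versus air, 22 higher and 9 lower, and 18 of them had a single symbol. An unadjusted p under 0.05 was reached by 3976 probe sets, where chance gives 1200 on average. Probe sets of the same animals vary together, so a count under chance can lie far from this average. The count was 4, 0 and 1 without air animal 28, 29 and 44, and 241, 385, 0 and 11 without medium animal 34, 39, 41 and 42. It was 53 in the brighter part of the probe sets, 0 with only the 2 groups fitted, 2 with the 8 complete animals, 100 with the RNA index as a covariate and 1037 with the arrays fitted under a random animal effect.

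Immediate early genes had the smallest camera p of the lists in medium versus air, with a median of 0.57 and 14 of 15 above 0 (adjusted p = 1.18e-06; adjusted p = 0.554 with an estimated correlation). No member was called over all probe sets, 0 of 15, and 9 passed adjusted over the list alone. These included FOS (1.28 ± 0.25), the orphan nuclear receptor NR4A3 (0.98 ± 0.25), EGR1 (0.87 ± 0.27) and JUN (0.71 ± 0.18), each encoding a transcription factor. Glucocorticoid responsive genes rose by a median of 0.55 with 13 of 13 above 0 (adjusted p = 0.00328; adjusted p = 0.554 with an estimated correlation). DUSP1 (0.78 ± 0.16), which both lists hold, was the 1 member to pass adjusted over the list alone, and the cochaperone FKBP5 had 1.07 ± 0.58 and the clock gene PER1 0.96 ± 0.46. The glucocorticoid median was 0.36 without medium animal 41 and 0.34 without 42.

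Coagulation and fibrinolysis genes rose by a median of 0.30, with 10 of 15 above 0 (adjusted p = 0.0252; adjusted p = 0.554 with an estimated correlation). F3 was called over all probe sets. Adjusted over the list alone 5 passed as higher, among them F3, THBS1 (0.54 ± 0.14), the protease inhibitor SERPINE2 (0.63 ± 0.17) and the urokinase gene PLAU (0.49 ± 0.15), and 1 as lower, the anticoagulant PROS1. Epithelial growth factor and wound genes rose by a median of 0.30 with 5 of 8 above 0 (adjusted p = 0.0437; adjusted p = 0.554 with an estimated correlation). Over all probe sets 0 of these were called, and 4 passed adjusted over the list alone: the EGF receptor ligands AREG (0.86 ± 0.19) and HBEGF (0.45 ± 0.13), the matrix protein TNC (0.60 ± 0.19) and PLAU. The coagulation call ended without air animal 28 (adjusted p = 0.0709) or medium animal 41 (median 0.17, adjusted p = 0.0978), and the wound gene call without air animal 28 (0.0709) or 29 (0.0798) or medium animal 34 (0.0563) or 39 (0.0843). Both ended with the 8 complete animals (0.25, adjusted p = 0.31 for coagulation, and 0.36, adjusted p = 0.0882 for wound genes).

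In medium versus air 2 lists passed camera as lower. T and NK cell markers fell by a median of 0.32 on the log2 scale, with 13 of 16 below 0 (adjusted p = 0.0252; adjusted p = 0.554 with an estimated correlation). The cytotoxic granule gene GNLY (-1.26 ± 0.29) and the T cell receptor subunit CD3E (-0.43 ± 0.12) passed adjusted over the list alone, and 0 over all probe sets. MHC class II and dendritic cell genes fell by a median of 0.20 on the log2 scale with 11 of 11 below 0 (adjusted p = 0.0285; adjusted p = 0.554 with an estimated correlation). In this list 0 members passed over all probe sets or adjusted over the list alone. Both calls ended without air animal 44 (adjusted p = 0.121 for each) or without medium animal 39 (0.268 for T and NK, 0.279 for MHC class II). Animal 39 had the highest RNA index, that is, the least intact RNA. Without animal 44 the medians were -0.32 and -0.16, without 39 they were -0.22 and -0.10, and without medium animal 34 the MHC class II median was -0.34. With the 8 complete animals, without medium animals 39 and 41, the medians were -0.09 and -0.08 and both calls ended (adjusted p = 0.54 for each). The MHC class II call also ended with the mean of all probe sets of a gene (-0.15, adjusted p = 0.0734). B and plasma cell markers (median -0.35, adjusted p = 0.0823) and mast cell markers (-0.52, adjusted p = 0.284) did not pass.

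Other lists did not pass in medium versus air. The 20 inflammatory cytokines and chemokines had a median of -0.11 and a mean of -0.02, while camera's direction was up (adjusted p = 0.927). Neutrophil markers had a median of 0.20 (adjusted p = 0.346). The 21 p53 target and DNA damage genes had a median of 0.11 (adjusted p = 0.229), of which PMAIP1 was called over all probe sets and 3 passed adjusted over the list alone. NRF2 targets and oxidative stress genes had a median of 0.02 (adjusted p = 0.596), which was -0.0016 with the deposited scaling. Alveolar type 2 and surfactant genes had a median of -0.21 (adjusted p = 0.229), and MUC1 was their only member called. Heat shock genes (0.16) and smooth muscle markers (0.12) each had an adjusted p of 0.0747. Of the markers of other tissue in the sample, striated and heart muscle had a median of 0.01 (adjusted p = 0.927), cartilage 0.08 (0.263) and erythroid genes 0.39 (0.229).

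**Figure D2:**
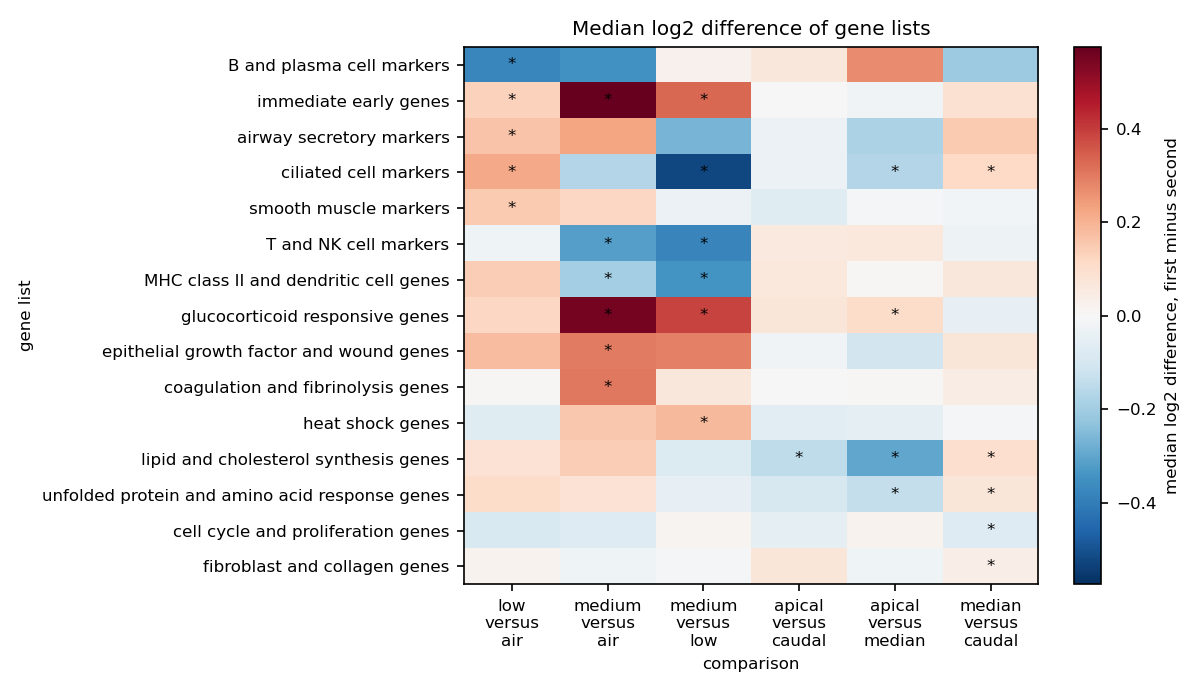
Median log2 difference, first group minus second, of the 15 gene lists that passed camera in at least 1 of the 6 comparisons; an asterisk marks an adjusted p under 0.05 at the preset correlation. Immediate early genes had a median of 0.57 in medium versus air and lipid and cholesterol synthesis genes -0.30 in apical versus median.

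The medium and low doses were compared directly. With limma 1 probe set was called, which has no symbol in the annotation and was chosen after its value was seen. It was 1.44 ± 0.11 higher with the medium dose (adjusted p = 0.0037, 4 against 3 animals). The genes with the smallest p were the fatty acid hydroxylase family member FAXDC2 (-0.59 ± 0.08), SH3GL3 (-0.74 ± 0.11), RCAN1 (0.60 ± 0.09), the protease BACE2 (0.63 ± 0.09) and NUDT6 (0.71 ± 0.11). None of the 5 passed (adjusted p = 0.0853 for each), while without medium animal 34 each did (adjusted p from 0.0189 to 0.0223). CXCL8 differed by 0.95 ± 0.18 (adjusted p = 0.0934) and CDKN1A by 0.66 ± 0.19 (adjusted p = 0.155), with 4 of 4 medium animals above the low mean, and both passed without medium animal 34 (1.12, adjusted p = 0.0157, and 0.83, adjusted p = 0.0258). All 7 genes passed under the random animal effect, which draws in part on lobes of the same animal (adjusted p from 0.000594 to 0.0123). IL6 differed by 0.25 ± 0.24, HMOX1 by 0.18 ± 0.17, SFTPC by 0.05 ± 0.06 and IL1B by 0.02 ± 0.11, the last of which was -0.01 with the deposited scaling. An unadjusted p under 0.05 was reached by 4372 probe sets. Without medium animal 34 there were 1373 calls, and with a random animal effect 1393. The count was 0 without low animal 31 or 33 and 2 without low animal 32 or with only the 2 groups fitted, 3 in the brighter part of the probe sets and 5 with trend and robust eBayes.

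In medium versus low, 6 lists passed camera. Ciliated cell markers fell by a median of 0.52 on the log2 scale with 7 of 7 below 0 (adjusted p = 0.00274; adjusted p = 0.62 with an estimated correlation). Adjusted over the list alone 4 passed, SPA17 (-0.85 ± 0.20), TEKT1 (-0.67 ± 0.16), CAPSL (-0.56 ± 0.16) and ROPN1L (-0.52 ± 0.12). Against air, the ciliated list had a median of 0.22 with the low dose and of -0.17 with the medium dose, where it did not pass. MHC class II and dendritic cell genes fell by a median of 0.34 on the log2 scale with 10 of 11 below 0 (adjusted p = 0.00434; adjusted p = 0.62 with an estimated correlation). The class II genes SLA-DMA (-0.58 ± 0.17), SLA-DMB (-0.56 ± 0.15) and SLA-DRB1 (-0.55 ± 0.14) passed adjusted over the list alone. T and NK cell markers fell by a median of 0.38 on the log2 scale with 14 of 16 below 0 (adjusted p = 0.00422; adjusted p = 0.62 with an estimated correlation). Glucocorticoid responsive genes rose by 0.39 with 13 of 13 above 0 (adjusted p = 0.0128; adjusted p = 0.62 with an estimated correlation). Heat shock genes rose by 0.19 with 13 of 14 above 0 (adjusted p = 0.00553; adjusted p = 0.62 with an estimated correlation) and immediate early genes by 0.33 with 14 of 15 above 0 (adjusted p = 0.00274; adjusted p = 0.62 with an estimated correlation). In these 4 lists 0 members passed adjusted over the list alone. In the 6 lists 0 members were called over all probe sets. Without low animal 32 the T and NK (adjusted p = 0.0701), glucocorticoid (0.0967) and heat shock (0.101) calls ended. The T and NK call also ended without medium animal 39 (0.0549) and the glucocorticoid call without 41 (median 0.22, adjusted p = 0.212) or 42 (0.18, adjusted p = 0.205). Without medium animal 34 the MHC class II median was -0.56 and the glucocorticoid median 0.60. The T and NK median was -0.25 without medium animal 41, and that of immediate early genes 0.19 without low animal 33. With the 8 complete animals the T and NK (-0.14, adjusted p = 0.299), MHC class II (-0.20, adjusted p = 0.0566) and heat shock (0.11, adjusted p = 0.192) calls ended. The glucocorticoid median was 0.18 with the mean of all probe sets of a gene. Airway secretory markers (-0.27, 8 of 11 below 0, adjusted p = 0.364) and alveolar type 2 genes (-0.20, 9 of 12 below 0, adjusted p = 0.0907) did not pass. Nor did monocyte and macrophage markers (median -0.11), mast cell markers (-0.65) or erythroid genes (0.46).

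Exposure was next compared within each lobe, with 1 array per animal. In the median lobe the medium dose (4 animals) differed from air (3 animals) at 97 probe sets, 56 higher and 41 lower, of which 44 had a symbol. The examples that follow were chosen after their values were seen. The cardiac natriuretic peptide gene NPPB rose by 1.32 ± 0.20 (adjusted p = 0.0411), the keratin gene KRT18 by 1.28 ± 0.20 (0.0411), and the stress gene GADD45G by 1.21 ± 0.13 (0.0308). F3 rose by 1.57 ± 0.26 (0.0453) and SERPINE2 by 0.98 ± 0.15 (0.0411). Genes of ribosome assembly among the calls were NOP56 (0.81 ± 0.14), RSL1D1 (0.73 ± 0.11), PAK1IP1 (0.72 ± 0.12) and LTV1 (0.63 ± 0.09). FBXO32 fell by 1.82 ± 0.27 on the log2 scale, the neuropeptide gene NMB by 1.00 ± 0.13 and the epoxide hydrolase EPHX1 by 0.69 ± 0.12. With median-centred arrays the split was 44 higher and 18 lower, of 62 calls, and with an offset of 1 it was 3 higher and 9 lower, of 12. The count was 238 in the brighter part of the probe sets and 0 with only the 2 groups fitted or with the complete animals. It was 0 without air animal 28 or 29 or medium animal 41, 8 without air animal 44, and 398, 11 and 4 without medium animal 34, 39 and 42.

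In the caudal lobe (3 medium and 3 air animals) 1 probe set was called, for THBS1, the matrix glycoprotein thrombospondin, and it rose by 1.69 ± 0.16 (adjusted p = 0.0458). It is not the brightest of the gene, which stands for THBS1 elsewhere, and was chosen after its value was seen. The same probe set differed by 1.71 ± 0.44 in the median lobe (adjusted p = 0.0973) and by 0.47 ± 0.43 in the apical lobe (adjusted p = 0.943). The caudal count was 5 in the brighter part of the probe sets, 4 with trend and robust eBayes and 0 with an offset of 1, with only the 2 groups fitted or with the complete animals. It was 244 without medium animal 34 and 0 without air animal 29 or 44 or medium animal 41 or 42. In the apical lobe FBXO32 differed by -1.52 ± 0.20 (adjusted p = 0.201) and F3 by 0.66 ± 0.28 (adjusted p = 0.857), and limma called 0 probe sets for the medium dose, with 1385 at an unadjusted p under 0.05. For the low dose limma called 0 in each lobe, with 1708 in the apical, 1665 in the median and 1460 in the caudal lobe at an unadjusted p under 0.05.

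Whether the response to exposure differed between lobes was tested with the interaction. The genes with the smallest p were the chromatin remodeler subunit EP400 (F = 10.1), the RNA polymerase I subunit POLR1E (8.65), the fucosyltransferase FUT1 (8.59), LETM1 (8.37), WDR34 (8.25) and PM20D2 (8.13), and none passed (adjusted p = 0.595 for each). F3 had an interaction adjusted p of 0.706 and FBXO32 of 0.865. With limma 0 probe sets were called and 1773 had an unadjusted p under 0.05, so no difference of the response between lobes was detected.

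Lobes of the same animals were compared to give the differences along the lung, over all exposure groups. Lipid and cholesterol synthesis genes were lower in the apical than in the median lobe by a median of -0.30, with 13 of 13 below 0 (adjusted p = 1.52e-07; adjusted p = 0.309 with an estimated correlation). Over all probe sets 5 were called, and 10 passed adjusted over the list alone. Among those called were FDPS (-0.68 ± 0.12, adjusted p = 0.0136, lower in 9 of 9 animals) and CYP51 (-0.46 ± 0.08, adjusted p = 0.0136, 9 of 9), both enzymes of sterol synthesis. SC5D (-0.42 ± 0.09, adjusted p = 0.0282, 8 of 9) and SQLE (-0.38 ± 0.07, adjusted p = 0.0181, 9 of 9) act in the same pathway. The fifth was its regulator SREBF2 (-0.30 ± 0.08, adjusted p = 0.048; chosen after its value was seen). ABCA1, which exports cholesterol from cells, was higher by 0.59 ± 0.09 (adjusted p = 0.0124, 9 of 9), and VLDLR, a lipoprotein receptor, by 0.46 ± 0.08 (adjusted p = 0.0162, 9 of 9; 0.22 in the 3 air animals alone).

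The largest named difference in apical versus median was that of ANKRD1, a muscle ankyrin repeat protein that also responds to YAP, at -1.55 ± 0.27 (signal 176 against 599, adjusted p = 0.0136, 8 of 9 animals). Next came the odorant binding protein OBP2B (-1.30 ± 0.30, adjusted p = 0.0334, 8 of 9) and PYCR1 (-0.92 ± 0.17, adjusted p = 0.018, 9 of 9). SERPINE2 (-0.79 ± 0.19) and the hyaluronan synthase SHAS2 (-0.69 ± 0.15, dim at signals of 10.1 against 25.5) were lower as well. Higher in the apical lobe were the tight junction gene CLDN11 (0.80 ± 0.15, adjusted p = 0.0153, 9 of 9), the extracellular superoxide dismutase SOD3 (0.69 ± 0.18, adjusted p = 0.0479, 7 of 9) and MXI1 (0.63 ± 0.12). The pyruvate dehydrogenase kinase PDK4 (0.63 ± 0.14) and RTN1 (0.62 ± 0.12) were also higher. CXCL8 was higher by 0.52 ± 0.13 (adjusted p = 0.038), HMOX1 by 0.31 ± 0.07, the plasma cell receptor TNFRSF17 by 0.39 ± 0.09 and the B cell receptor subunit CD79B by 0.27 ± 0.07. The p53 targets DDB2 (0.41 ± 0.10) and PPM1D (0.20 ± 0.05), the interferon gene IFI44L (0.24 ± 0.06) and the carbonic anhydrase CA9 (0.17 ± 0.05) were higher too. Of 2 further probe sets for DDB2, 1 pointed the same way. Lower were the keratins KRT18 (-0.53 ± 0.14) and KRT19 (-0.43 ± 0.09), the dim cardiac actin ACTC1 (-0.45 ± 0.10, signal 16.1 against 26.9) and THBS1 (-0.38 ± 0.10). So were the chaperone HSPA4 (-0.26 ± 0.06), the surfactant protein SFTPD (-0.23 ± 0.06) and the replication factor MCM3 (-0.21 ± 0.06). In the 3 air animals alone KRT18 differed by -0.05 and SFTPD by -0.01, with 2 of 3 animals below 0 for each. Also smaller there by over 1.5 times were CLDN11 (0.52), MXI1 (0.31), RTN1 (0.41), SHAS2 (-0.34), DDB2 (0.26), PPM1D (0.12), HSPA4 (-0.12) and MCM3 (-0.12). Whether the exposed animals differed from air in this was tested by the interaction, which did not pass for KRT18 (adjusted p = 0.719), SFTPD or HSPA4 (0.646 for each).

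**Figure D3:**
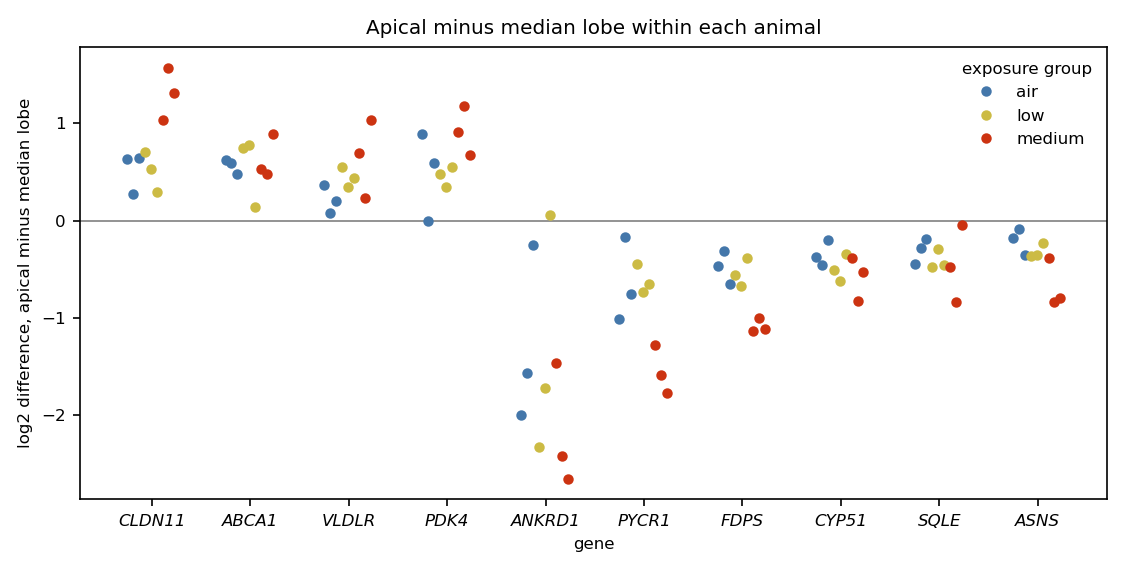
Log2 difference of the apical minus the median lobe within each of 9 animals (points, coloured by exposure group) for 10 genes called in this comparison. CLDN11, ABCA1 and VLDLR were above 0 and PYCR1, FDPS, CYP51, SQLE and ASNS below 0 in 9 of 9 animals.

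Other lists passed in apical versus median. Unfolded protein and amino acid response genes were lower by a median of -0.14, with 14 of 16 below 0 (adjusted p = 0.00174; adjusted p = 0.478 with an estimated correlation). The asparagine synthetase ASNS (-0.40 ± 0.08; -0.21 in the 3 air animals alone), the chaperone partner SDF2L1 (-0.53 ± 0.12) and the transcription factor XBP1 (-0.19 ± 0.04) were called lower and VLDLR higher, and adjusted over the list alone 7 were lower and 1 higher. Glucocorticoid responsive genes were higher by a median of 0.11 with 13 of 13 above 0 (adjusted p = 0.00174; adjusted p = 0.309 with an estimated correlation), of which PDK4 was called and 4 passed adjusted over the list alone. Ciliated cell markers were lower by a median of -0.17 with 7 of 7 below 0 (adjusted p = 0.0295; adjusted p = 0.622 with an estimated correlation). Of these 0 were called over all probe sets and 1 passed adjusted over the list alone. The call ended without air animal 29 (adjusted p = 0.0839), low animal 31 (0.091) or 32 (0.0762), or medium animal 34 (0.0908).

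With limma and the animal as a block, 579 probe sets were called in apical versus median, 341 higher and 238 lower, of which 3 reached a 2-fold difference, and 39 were called without the animal block. With median-centred arrays 348 were higher and 145 lower. The count was 1010 in the brighter part of the probe sets, 205 with an offset of 1, 46 in the 8 complete animals and 0 in the 3 air animals alone (1518 at an unadjusted p under 0.05). It was 148 and 63 without air animal 28 and 44, 253 without low animal 32, and 33, 65, 382 and 38 without medium animal 34, 39, 41 and 42.

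Between the apical and caudal lobes, compared in 8 animals with both, FBXO32 was higher in the apical lobe by 0.64 ± 0.11 (adjusted p = 0.0279, 8 of 8 animals). The TGF beta coreceptor TGFBR3 was higher by 0.49 ± 0.08 (adjusted p = 0.0169, 8 of 8) and ITIH2 by 0.52 ± 0.10 (adjusted p = 0.0412, 8 of 8). The neuropeptide Y receptor NPY1R (0.45 ± 0.09), the calcium binding protein S100B (0.37 ± 0.07) and TMEM86A (0.34 ± 0.07) were also higher. In the 3 air animals alone TGFBR3 differed by 0.31, ITIH2 by 0.27, S100B by 0.16 and TMEM86A by 0.21. ACTC1 was lower by -0.71 ± 0.11 (adjusted p = 0.0169, 8 of 8), at mean signals of 16.1 against 36.2, not far from the added offset of 16. Also lower were the replication helicase subunits MCM5 (-0.32 ± 0.06) and MCM3 (-0.29 ± 0.06), the collagen COL15A1 (-0.26 ± 0.05) and TMEM167A (-0.33 ± 0.07). Of 2 further probe sets for MCM5, 1 pointed the same way. Lipid and cholesterol synthesis genes were lower by a median of -0.15 with 12 of 13 below 0 (adjusted p = 0.000384; adjusted p = 0.619 with an estimated correlation). Of these 0 were called over all probe sets and 6, such as FDPS (-0.47 ± 0.13) and SREBF2 (-0.34 ± 0.08), passed adjusted over the list alone. Limma called 40 probe sets with the animal as a block, 27 higher and 13 lower, and 1 without the block. Other settings gave 19 (median-centred or deposited scaling), 152 (brighter part), 5 (offset of 1), 82 (trend and robust), 92 (random block), 15 (RNA index), 17 (complete animals) and 0 (air animals alone, with 1215 at an unadjusted p under 0.05). Leaving out 1 animal gave 21, 21 and 11 for air 28, 29 and 44, 66, 1 and 12 for low 31, 32 and 33, and 2, 13, 17 and 14 for medium 34, 39, 41 and 42.

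The median and caudal lobes, compared in 9 animals, differed least by count of called probe sets, though not by count of lists. COL15A1 differed by -0.29 ± 0.05, MSANTD4 by -0.26 ± 0.05, RTN1 by -0.67 ± 0.12, the endothelial adhesion gene ICAM2 by -0.21 ± 0.04 and the adhesion receptor ADGRG1 by -0.43 ± 0.08. None of the 5 genes passed (adjusted p = 0.0814 for each), while MSANTD4 did without medium animal 41 (-0.29, adjusted p = 0.0409). Limma called 0 probe sets with the animal as a block and 0 without it, while 2786 had an unadjusted p under 0.05. Of the lists, 5 passed camera. Ciliated cell markers had a median of 0.11 with 7 of 7 above 0 (adjusted p = 0.0231; adjusted p = 0.646 with an estimated correlation). Lipid and cholesterol synthesis genes had 0.10 with 11 of 13 above 0 (adjusted p = 0.0375; adjusted p = 0.648 with an estimated correlation). Unfolded protein and amino acid response genes had 0.07 with 15 of 16 above 0 (adjusted p = 0.0498; adjusted p = 0.646 with an estimated correlation). Fibroblast and collagen genes had 0.04 with 14 of 17 above 0 (adjusted p = 0.0369; adjusted p = 0.646 with an estimated correlation). Cell cycle and proliferation genes had -0.07 with 21 of 25 below 0 (adjusted p = 0.0231; adjusted p = 0.646 with an estimated correlation). TEKT1 (0.28 ± 0.08) was the only member to pass adjusted over the list alone, and 0 passed over all probe sets. Each of the 5 calls ended without air animal 29 (adjusted p from 0.0651 to 0.0712) or medium animal 34 (0.0507 to 0.0834), and between 1 and 4 of them without air animal 28 or 44, low animal 31 or medium animal 39 or 42. The lipid median was 0.06 without low animal 31, the fibroblast median 0.07 without low animal 32 and 0.06 without 33, and the ciliated median 0.18 without medium animal 42.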

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

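Among the tests in this part, those with the RNA index as a covariate, of the heart muscle markers, of the mean of 4 airway lists and of a single animal as the whole source were chosen only after the result was seen.

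Values that stood apart from the rest of their group, by the gap to the nearest animal relative to the whole range, were found in 7 of the 76 groups tested, and chance gives such a value in about 5% of groups. In the medium group, PMAIP1 was 7.59 (log2) in animal 42 against 7.01 to 7.07 in the other 3 animals, and PYCR1 was 7.64 in animal 39 against 7.30 to 7.33. TSKU was 8.78 in animal 42 against 9.002 to 9.024, PNPT1 was 6.94 in animal 34 against 6.92 in each of the others, and COL8A1 was 6.75 in animal 41 against 6.57 to 6.60. In animal 42 the apical minus caudal difference of MCM5 was -0.58, with -0.36 to -0.18 in the other animals, and the apical minus median difference of MCM3 was -0.70, with -0.28 to -0.07 in the others. Outside the main measurement, the 3' to 5' signal ratio of the actin control was 3.32 in the apical and 4.69 in the median lobe of medium animal 39, above the range of 1.14 to 2.79 of the air arrays.

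The first pattern is the 31 probe sets called in medium versus air. Lower RNA integrity shared by the medium animals is argued against by the RNA index. It was 0.66, 1.25 and 0.84 in animals 34, 41 and 42, against 0.97 to 1.35 in air animals. Only animal 39, at 2.22, lay above, and without it the 31 probe sets were all called among 385. With the index as a covariate the median share of the log2 difference kept was 1.00 (quartiles 0.984 to 1.01). All 31 were then called among 100. That share was largely set beforehand, since the index differed by only 0.12 between the groups. Called probe sets are also those where the animals of a group agree. Whether a single animal is the source cannot be told from the kept share. Its lowest median was 0.974 (quartiles 0.939 to 0.991), without air animal 29. With so few animals a probe set is called only where the animals of a group agree, so the share was largely set by that choice. The number of calls was 0 without air animal 29, with 2 air animals left, and 0 without medium animal 41. Chance could not be excluded, since 4 of 35 splits of the 7 animals gave as many calls as the real 31. The highest others gave 195 and 156, several times the real count, which points to a structure of the samples. Both kept the 3 air animals together, joined by medium animal 39 or 34, and so contain much of the dose difference. The remaining split, with 36 calls, broke up the air group: air animal 44 was placed with medium animals 39, 41 and 42, and medium animal 34 with the air animals. An effect of the dose may underlie the calls as a hypothesis, and batches, which the labels do not give, stay open.

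The second pattern is the 579 probe sets called in apical versus median. Lower RNA integrity in one lobe is argued against by the RNA index, which differed by -0.0041 ± 0.112 between the lobes. The kept share of 1.00 with the index as a covariate follows from this and adds nothing. Whether more airway wall in the median lobe is the source cannot be told from the kept share. This share was 1.11 (quartiles 1.03 to 1.20) with the ciliated marker mean as a covariate. With that covariate 603 probe sets were called, 351 of them among the 579. The share was 1.13 (1.04 to 1.23) with the mean of the ciliated, secretory, basal and cartilage lists. A mean of few genes may follow the airway wall only in part, so such a covariate can leave a difference in airway wall in place. The ciliated, secretory, basal and cartilage lists had medians of -0.17, -0.18, -0.15 and -0.14, the direction that this explanation calls for. Heart muscle in the median lobe sample cannot be told apart, since the 13 striated and heart muscle genes had a median signal of 17.6, near the floor, with a median of -0.010 (quartiles -0.07 to 0.05; 0.0060 with median-centred arrays), while ACTC1 among them was called lower. Only 1 of 100 splits, the real one, gave as many calls as the real 579. Another gave 553, nearly the real count, so the splits do not clearly exclude chance. A difference between the lobes themselves and other differences in how they were sampled stay open and untested. A larger lobe difference with the medium dose stays open too, although the interaction called 0 probe sets. For FDPS, apical minus median was -1.13, -1.01 and -1.11 in medium animals 34, 39 and 42, against -0.31 to -0.68 in the others. For ABCA1 it was 0.53, 0.47 and 0.89, against 0.14 to 0.78. These 2 genes were chosen after their values were seen.

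The third pattern is the immediate early gene list in medium versus air. Animal means relative to the air mean were 0.02, -0.23 and 0.22 in air, 0.29, 0.36 and 0.08 in low and 0.40, 0.47, 0.73 and 0.63 in medium animals. Lower RNA integrity as the whole source is argued against by medium animals 34 (0.40) and 42 (0.63), which lay above each air animal. Their RNA index was 0.66 and 0.84, more intact than the 0.97 to 1.35 of the air animals. The share of the list's mean difference kept with the index as a covariate was 0.993. This share says little, since the index differed by only 0.12 between the groups. A single animal as the whole source is argued against, since the lowest mean difference without 1 animal was 0.44 (2 SE either side, 0.19 to 0.69), without air animal 29, and each medium animal lay above each air animal, but a part played by that animal cannot be told apart with so few animals (share kept 0.789, up to 1.19 without others). Chance could not be excluded, since 2 of 35 splits gave a camera p as small as the real 3.28e-08 (smallest other 2.88e-08), and handling of the animals before sampling may move such genes too but was not recorded.

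Splits of the samples were also counted for the other comparisons. Chance is argued against for apical versus caudal (1 of 100 splits, the real one with 40 calls, highest other 6). It could not be excluded for medium versus air in the median lobe (2 of 35, real 97, highest other 131). For median versus caudal (highest other 69) and the interaction (highest other 4) the real count was 0, which each of the 100 splits reaches, so the splits decide nothing. Chance could not be excluded for medium versus low either (2 of 35, real 1). There the highest other split, with medium animal 34 placed among the low animals, gave 1942 calls, many times the real count. This points to a structure of the samples in which animal 34 lies with the low animals at many probe sets. It did not at all of them: CXCL8 and CDKN1A were higher in each of the 4 medium animals than in each low animal. Without animal 34 the calls were 241 in medium versus air and 1373 in medium versus low. A lower delivered dose or processing together with the low animals may underlie the place of animal 34, as a hypothesis, but neither was recorded or tested. For the comparisons of 3 with 3 animals the 10 splits are too few for a share under 0.05. They were low versus air (real 0, highest other 0), low versus air in the apical (0 and 0), median (0 and 3) and caudal lobe (0 and 0), and medium versus air in the apical (0 and 4) and caudal lobe (1 and 2). As many calls came in 10 of the 10 splits where the real count was 0, as they must, and in 2 of 10 for medium versus air in the caudal lobe.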

How the results depend on the processing

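The deposited scaling, the RNA index as a covariate, gene lists under other scalings, and the 8 complete animals for lobe, within-lobe, interaction and list tests were chosen only after the result was seen. Quantile normalization, planned as an alternative, was the main choice, and the deposited scaling took its place. For named genes and lists that were called, 674 comparisons with an alternative chosen beforehand kept direction and call, and 556 kept direction but not the call. With alternatives added later these were 164 and 74. No called gene or list reversed its direction in these. For those not called, 431 comparisons with alternatives chosen beforehand and 67 with those added later stayed so, and 20 of the former passed.

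Calls in medium versus air were 53 in the brighter part of the probe sets, where fewer are tested, 1037 with the arrays under a random animal effect, 0 with only the 2 groups, 2 with the 8 complete animals and 100 with the RNA index. In medium versus low they were 3 (brighter part), 5 (trend and robust eBayes), 1393 (random animal effect) and 2 (only the 2 groups), and in low versus air 28 (random animal effect). In the median lobe, calls in medium versus air were 62 (median-centred arrays), 238 (brighter part), 12 (offset of 1), 0 (only the 2 groups) and 0 (complete animals), and in low versus air 1 (offset of 1). In the caudal lobe they were 5 (brighter part), 0 (offset of 1), 4 (trend and robust), 0 (only the 2 groups) and 0 (complete animals). The random animal effect draws in part on lobes of the same animal, with 1 consensus correlation for all probe sets, which can raise its counts and lower its p. Apart from this, the brighter part and the settings with fewer animals, the cause was not tested.

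Calls in apical versus caudal were 19 with median-centred arrays and 19 with the deposited scaling, 152 (brighter part), 5 (offset of 1), 82 (trend and robust), 1 (no animal block), 92 (animal as a random block), 0 (3 air animals), 15 (RNA index) and 17 (complete animals). In apical versus median they were 1010 (brighter part), 205 (offset of 1), 39 (no animal block), 0 (3 air animals) and 46 (complete animals), and in median versus caudal 2 (complete animals). The interaction gave 0 calls in every setting with all animals. The cause was not tested beyond the number of animals or probe sets.

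Gene lists that passed numbered 0 in each of the 6 contrasts with an estimated correlation. With the complete animals they numbered 2 in medium versus air, 3 in medium versus low, 4 in apical versus caudal and 1 in median versus caudal.

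Leaving out 1 animal in turn gave 0 to 2 calls in low versus air, 0 to 385 in medium versus air, 0 to 1373 in medium versus low, 1 to 66 in apical versus caudal, 33 to 570 in apical versus median, 0 to 3 in median versus caudal and 0 to 1 in the interaction. Within lobes it gave for the low dose 0 to 0 (apical), 0 to 1 (median) and 0 to 1 (caudal), and for the medium dose 0 to 1, 0 to 398 and 0 to 244. Lists that passed ranged from 1 to 6 in low versus air, 4 to 7 in medium versus air, 3 to 6 in medium versus low, 1 to 4 in apical versus caudal, 3 to 10 in apical versus median and 0 to 9 in median versus caudal.

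The direction reversed for 3 genes that were not called. SFTPC in low versus air was -0.10 with median-centred arrays, -0.072 with the deposited scaling and -0.0026 with the RNA index. Without 1 animal it ranged from -0.027 to 0.050 and was below 0 without air animal 28 (-0.0024) or 29 and without low animal 31 (-0.0053). IL1B in medium versus low was -0.013 with the deposited scaling, -0.096 with the complete animals and -0.029 with the RNA index. Without 1 animal it ranged from -0.057, without medium animal 41, to 0.078. HMOX1 in medium versus air ranged from -0.13, without air animal 29, to 0.16, and was -0.051 without medium animal 34. The deposit held no detection calls, so how far dim signals stood above background was not known; the offset of 1 gives these more weight than the offset of 16.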

Other observations

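The tests in this part, of ribosome assembly genes, of genes induced by YAP and TEAD and of the shared direction of genes, were chosen only after the result was seen.

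Ribosome assembly genes, which process ribosomal RNA and build the subunits in the nucleolus, were listed because some were seen among the calls. Of 40 genes listed, 32 were measured, and 10 of these had been seen before the list was written. In medium versus air 29 of 32 were above 0 with a median of 0.30 and 0 called, such as NOP58 (0.42 ± 0.06) and the nucleostemin gene GNL3 (0.65 ± 0.13). In apical versus median 30 of 32 were below 0 with a median of -0.25 and 11 called lower, such as MRTO4 (-0.46 ± 0.08) and GRWD1 (-0.44 ± 0.08). A hypothesis is that this group was higher with the medium dose (camera p = 2.14e-13; p = 0.00533 with an estimated correlation) and higher in the median lobe (camera p = 1.59e-12; p = 0.0485 with an estimated correlation). Over the 22 genes not seen before, the medians were 0.20 for the dose, with 0 called, and -0.19 for the lobe, with 4 called. There camera p was 6.98e-08 for the dose (p = 0.0129 with an estimated correlation) and 2.21e-07 for the lobe (p = 0.0789 with an estimated correlation). The values may be read as a hypothesis only, since the list was written from these data.

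Genes induced by YAP and TEAD, which respond to mechanical load, were listed because some, such as ANKRD1, F3 and THBS1, were seen to be high. NPPB, also listed, was among the calls in the median lobe given above. In medium versus air 12 of the 13 measured were above 0 with a median of 0.50, against 0.11 over the 9 not seen before. Among them were ANKRD1 (1.77 ± 0.36), CYR61 (0.76 ± 0.24) and NPPB (0.82 ± 0.16), and F3 was the 1 called. The hypothesis that they were higher in the medium group had a camera p of 2.33e-06 (p = 0.0161 with an estimated correlation), which includes the genes seen to be high. Over the 9 genes not seen before, camera p was 0.00978 (p = 0.0806 with an estimated correlation). The hypothesis that they were higher in the median lobe was not borne out, with a limma camera p of 0.545 over 13 genes, although ANKRD1 and THBS1 were called there.

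The differences of medium minus air and of median minus apical lobe were correlated across 6765 genes (Pearson r = 0.339, Spearman rho = 0.335), where genes are not independent replicates. Of 35 splits of the medium and air animals, 1 gave a correlation as large, the real one, and the highest other was 0.333, nearly the same, while both differences came in part from the same arrays. With the lobe difference taken from the 3 low animals and the dose difference from the 5 complete medium and air animals, r was 0.22, with 0.208 as the highest other. The 10 splits of these 5 animals, of which 1 gave as large an r, are too few for a share under 0.05. Whether the 2 differences share a direction stays open.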
